A study of Mus musculus with 2 samples.

How the data were processed

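The samples were 2 biological replicates of newborn (age 0 days) mouse stomach, strain B6NTac;B6NCrl/Lap, each a pool of both sexes, immunoprecipitated for H3K4me3, per the labels. The labels number the replicates, give each its own tissue sample and the same donor entry, and state fragments of 300 to 500 bp. Per the labels, the pool of replicate 1 held 15 mice, and no number is given for replicate 2. All values came from peak lists that the authors deposited, in mm10 per the descriptions deposited with the samples. These describe a list for each replicate, a list for both replicates pooled, and a list of replicated peaks derived from the other 3. They also cite 1 more source file for the list of replicate 1 than for that of replicate 2, without stating its kind. The aligner, the peak caller, its threshold and the overlap rule behind the replicated list are not given in the sources used here. Signal tracks and alignments were not used here.

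Each peak has a fold enrichment, a linear ratio over background that the authors deposited per peak, and this value is the authors' own. Each peak also has a −log10 p and a −log10 q value, as deposited by the authors in the narrowPeak columns. The smallest −log10 p was 2.06, 2.02, 2.03 and 2.24 in the lists of replicate 1, replicate 2, the pool and the replicated peaks. Peaks with −log10 q under 2 made up 13.8% of replicate 1, 9.90% of replicate 2 and 1.00% of the replicated list. The lists covered 30.6, 30.9, 34.3 and 33.0 Mb in this order, with median widths of 757, 984, 1032 and 1303 bp and median folds of 7.18, 11.5, 10.5 and 17.0. No list holds read counts, so the depth of the libraries is unknown, and Wilson intervals (95%) describe counting over peaks or genes, not over animals. Every replicated peak was also in the pooled list, and all 20816 pooled peaks that overlapped both replicate lists were replicated. A further 1846 replicated peaks did not overlap both lists by the rule below, with 773 overlapping replicate 1 alone, 919 replicate 2 alone and 154 neither.

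Peaks were compared with bedtools 2.31.1, and a peak counted as shared when at least 50% of either peak was covered. For values of matched peaks, each peak was paired with the partner of largest overlap in both directions. The share from chance was taken from 100 random placements of a list within its chromosomes, with peak widths kept. Starts of all transcripts of protein-coding genes came from GENCODE M21, and a promoter peak was a peak within 1000 bp of a start. A gene's value was the highest fold in that window, so a gene can receive the peak of a neighbour. Domains were made by closing gaps of up to 1000 bp between peaks, the widest 5% were called broad, and a gene was assigned to a domain that held a start. The CpG observed over expected ratio was computed over 500 bp each side of the gene's 5′ end in the reference sequence. Peaks on scaffolds (14 of the replicated list) were kept in the peak counts and had no annotated start.

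The 27 gene lists were written from general knowledge. They covered housekeeping and cell cycle genes, gastric endoderm regulators, surface and neck mucous, parietal, chief and gastric endocrine cells, squamous forestomach, smooth muscle, gastric mesenchyme, enteric neurons and glia, interstitial cells of Cajal, endothelium, mesothelium, immune and erythroid cells, hepatocytes, pancreas, intestine, cardiac muscle, skeletal muscle, lung and thyroid, forebrain, germ cells, developmental regulators of other lineages, Hox genes, and the olfactory, vomeronasal and keratin-associated families. Of their genes, 5 stood in more than 1 list (Satb2, Hand2, Hnf4g, Pax7 and Lhx2). Older symbols were matched to current ones for Mucl3 and Tnfrsf19, and a symbol without a match was left out. Each list was tested against all other protein-coding genes with a two-sided Fisher's exact test in scipy 1.17.1, with Benjamini-Hochberg adjustment over the 27 lists and a threshold of 0.05. The test of broad domains was the same, over genes with a start in a domain.

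For the difference between replicates, log2 fold enrichments of genes with a promoter peak in both were subtracted (replicate 1 minus replicate 2) and centred on their median. The median of each list with at least 5 such genes was placed among 10000 random lists of the same size matched on mean height in 20 bins. With 1 library per replicate this describes those libraries, and no p-value was computed. The CpG comparison drew 10000 random lists matched on the CpG ratio in 20 bins. The Hox groups were compared with a permutation test of 100000 resamples.

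The lists, the groups, the main tests, the named-gene rule and most alternatives were fixed before the data were examined. The split of Hox genes, the CpG-matched tests of peak height and of endocrine genes alone, and the CpG ratio at the richest start were chosen after values had been seen. The named genes were the 2 members of each list with the highest promoter fold and the first 2 without a promoter peak, the 10 protein-coding genes with the widest domains, the 5 genes with the largest difference in each direction between the replicates, and all Hox genes. Other genes are named with a statement that their values had been seen. The alternatives changed the overlap rule, the peak threshold, the window, the choice of starts, the peak list, the gene background, the gap and width of domains, and the centring and value of the replicate comparison. A further 4 settings, making 7 alternatives over the separate results, were added after the data had been seen: −log10 q of at least 5 in the counted list alone, the start inside the peak, only peaks at the starts of 1 gene, and matched peaks over a start.

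The procedures were tested on simulated data. With 49.5% of 22648 peaks planted as overlapping, 50.1% were recovered. Lists in which all members had a planted peak were called in 100% of draws over 21938 genes, lists with peaks planted at 20% of members in 94.5%, and lists without an effect in 0.333%. In the replicate comparison over 14537 genes, a planted list shift of 0.5 was found outside the random range in 100% of draws and no shift in 6.31%. In both tests of lists, effects were planted only in lists of at least 14 genes, so recovery in smaller lists was not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.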

Results

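Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark found at the starts of active genes and of genes poised for activity, was measured by ChIP-seq in whole stomach of newborn mice. The series held 1 group with 2 biological replicates, each a pool of stomachs from male and female mice. Per the labels, replicate 1 came from 15 mice, and no number is given for replicate 2. Whole stomach holds epithelium, smooth muscle, connective tissue, nerves and vessels, so each peak is a mixture over these cells. The data were 4 peak lists, with 29618 peaks in replicate 1, 26162 in replicate 2, 27287 in the pooled list and 22662 in the list of replicated peaks. The lists give each peak a fold enrichment but no read counts, so the depth of each library is unknown. With no second condition, the comparisons were between groups of genes within the replicated list and between both replicates. Fold values below are from the replicated list unless a replicate is named, and no SD is given because each replicate contributes 1 value.

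Transcription factors of the gastric endoderm, genes of smooth muscle and genes of the gastric mesenchyme all carried H3K4me3 at their promoters. A promoter peak was found at 20 of 20 endoderm factors (19 in the list of replicate 2), 15 of 15 smooth muscle genes and 20 of 20 mesenchymal genes, against 66.6% of all protein-coding genes. Klf5, an epithelial transcription factor, had a fold enrichment of 41.8 (28.6 in replicate 1 and 39.9 in replicate 2), and Foxa3, a forkhead factor of the endoderm, was assigned 48.9 from a peak that lay at the start of its neighbour Sympk, while the peak over its own start had 12.1. In smooth muscle, Srf, a regulator of actin and muscle genes, had 53.9 (40.5 and 49.98) and Smtn, a cytoskeletal protein of contractile smooth muscle, 33.5 (23.4 and 31.9). In the mesenchyme, the Hedgehog receptor gene Ptch1 had 45.5 (32.6 and 45.2) and the homeobox gene Isl1 had 36.9 (25.01 and 32.7). These were the 2 highest members of each list, and the median folds of the lists were 16.1, 16.7 and 18.5, against 31.8 over all genes with a peak (percentiles 0.04, 0.37 and 0.4 of random lists of the same size). By two-sided Fisher's exact test, adjusted over the 27 lists by the Benjamini-Hochberg method, the p-values were 0.00376 for endoderm factors, 0.01001 for smooth muscle and 0.00376 for mesenchyme. These tests run over genes of 1 peak list and say nothing about variation between animals.

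Genes that mark the differentiated cells of the gastric epithelium were divided between those with and those without a peak. Among genes of surface and neck mucous cells, 6 of 12 had a promoter peak (4 in both replicate lists), including Cldn18, a tight junction claudin, at 12.96 and Muc1, a membrane mucin, at 10.8 in a peak shared with the starts of Mtx1 and Thbs3. The secreted mucin gene Muc5ac and the gastrokine gene Gkn1 had none. Among parietal cell genes 9 of 12 had a peak, with Slc4a2, an anion exchanger, at 30.0 in a peak shared with Cdk5 and the creatine kinase gene Ckb at 27.7, whereas the proton pump subunit gene Atp4b and the potassium channel subunit gene Kcne2 had none. Of the chief cell list 6 of 10 had a peak, led by Tnfrsf19 at 26.2 (17.4 in replicate 1 and 24.1 in replicate 2) and Lgr5, a receptor of gastric stem cells, at 13.8, and Gif (gastric intrinsic factor) and the chitinase gene Chia1 had none. Of gastric endocrine genes 6 of 15 had a peak, with the transcription factor genes Insm1 at 14.4 and Pax6 at 7.65, and the hormone genes Gast (gastrin) and Sst (somatostatin) had none. Of genes of the squamous forestomach 10 of 14 had a peak, with Perp, a desmosome gene, at 22.1 and the cornified envelope gene Lor at 32.1 in a peak that did not reach its start, and the keratin genes Krt4 and Krt6a had none. Median folds of the members with a peak were 5.96 for mucous, 11.9 for parietal, 6.50 for chief, 5.96 for endocrine and 6.23 for squamous genes. In the main setting none of these 5 lists differed from other genes by Fisher's exact test, with adjusted p of 0.286 for mucous, 0.816 for parietal, 0.816 for chief, 0.0801 for endocrine and 0.816 for squamous genes. This depended on the setting, since endocrine genes were called below other genes with the start inside the peak (0.0260) and without the silent families in the background (0.0298), and mucous genes with the start inside the peak (0.0213).

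Promoter peaks at genes of other cell types of the stomach wall ranged from all genes of a list to fewer than 40%. Interstitial cells of Cajal, the pacemaker cells of gut motility, had a promoter peak at 6 of 6 genes, with Etv1 at 29.3 and the receptor tyrosine kinase gene Kit at 27.8. Endothelial genes had one at 13 of 15, with the VEGF receptor gene Kdr at 27.3 and the lymphatic regulator Prox1 at 19.3 (10.2 in replicate 1 and 21.6 in replicate 2), while Tie1 and Lyve1 had none in the replicated list. Enteric neurons and glia had one at 12 of 15 genes, with Hand2 at 26.7 and the neuronal RNA-binding protein gene Elavl4 at 23.8, while Plp1 and S100b had none there. Tie1 and S100b did have a peak in replicate 2 but not in replicate 1, at 3.43 and 2.60. Mesothelial genes had one at 3 of 8, with Krt19 at 10.8 and Lrrn4 at 13.3 in a peak beside its start (no promoter peak in replicate 1 and 10.97 in replicate 2), and Msln and Upk3b had none. Median folds were 25.5, 10.8, 12.6 and 10.8 for interstitial, endothelial, enteric and mesothelial genes. By two-sided Fisher's exact test none of the 4 lists differed in the main setting from other genes, with adjusted p of 0.242, 0.226, 0.484 and 0.181 in this order. For interstitial genes the test could not call an excess. The share of 6 of 6 is the highest possible, and its unadjusted p by Fisher's exact test was 0.188. In alternative settings mesothelial genes were called below other genes with 500 bp each side (0.0383) and with the start inside the peak (0.0411), and endothelial genes above with only peaks at the starts of 1 gene (0.0344).

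Genes of hepatocytes, pancreas, skeletal muscle, lung and thyroid, blood and immune cells and germ cells were mostly without a promoter peak, unlike forebrain and cardiac genes. The peak was present at 4 of 15 hepatocyte genes (Fisher's exact test, adjusted p = 0.00556), 3 of 14 pancreatic genes (0.00383), 5 of 14 skeletal muscle genes (0.0380), 3 of 10 lung and thyroid genes (0.0380) and 2 of 12 germ cell genes (0.00376). Alb and Apoa1 of hepatocytes, Cela1 and Cela2a of the exocrine pancreas, the myogenic factors Myog and Myf5, the lung surfactant genes Sftpc and Sftpb, and Ddx4 and Sycp3 of germ cells all lacked a peak. With 2000 bp each side, however, Sftpc was assigned a peak at 39.5 and Apoa1 one at 6.22. Immune genes had one at 5 of 16 (0.0126) and erythroid genes at 4 of 13 (0.0291), shares close to those at their CpG ratio (29.8% and 29.99%), with Ptprc (CD45), Cd68, the erythroid factor Gata1 and the globin gene Hbb-bt among those without. Of 1521 olfactory receptor, vomeronasal receptor and keratin-associated protein genes, 3 had a peak, with Vmn1r4 at 34.9 in a peak shared with Nt5c3 and Olfr94 at 13.3 in a peak beside its start.

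Among the genes of these lists that did have a peak, several shared it with a neighbour. The highest value of the hepatocyte list, Apoh at 38.6 (28.4 in replicate 1 and 19.5 in replicate 2), lay in a peak at the start of Prkca. The skeletal muscle genes Mylpf (46.2) and Actn3 (42.9) had peaks at the starts of Tbc1d10b and Zdhhc24, and Gdf9 (37.0, with 23.4 in replicate 1 and 38.3 in replicate 2), an oocyte growth factor, had one at the start of Uqcrq. Without the receptor and keratin-associated families, where 2 of 3 genes with a peak shared it, 5 of 26 genes with a peak (19.2%) shared it with another protein-coding gene, against 20.2% of all genes with a peak. Peaks of their own were found at Cd14 (21.8) and Coro1a (7.29) of the immune list, Gypa (14.2) of the erythroid list, the islet factors Mafa (15.3) and Nkx6-1 (12.8, with 7.57 in replicate 1 and 13.5 in replicate 2), Ttr (6.58), the ciliogenesis factor Foxj1 (29.8) and Dazl (11.3). For Klf1, the erythroid factor at 32.3, and Pax8 at 6.41, the peak did not reach the start. The call of the lung and thyroid list ended in 3 of 10 alternative settings, with adjusted p from 0.00925 to 0.273, and that of skeletal muscle in 2 (0.00494 to 0.148). With only peaks at the starts of 1 gene the calls of the immune and erythroid lists also ended, at adjusted p of 0.134 (alternatives from 0.000251 to 0.134) and 0.157 (0.00861 to 0.157).

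Genes of the intestine and of cardiac muscle were not separated from other genes by Fisher's exact test in the main setting, with adjusted p of 0.163 and 1, although the intestinal list was called below other genes with −log10 q of at least 5 (0.02895) and with the start inside the peak (0.0104). The intestinal list had a peak at 7 of 15 genes, with the chromatin regulator Satb2 at 30.3 (19.7 in replicate 1 and 31.03 in replicate 2) and the nuclear receptor gene Hnf4g at 8.71, and the fatty acid binding protein genes Fabp1 and Fabp2 had none. The cardiac list had a peak at 8 of 12 genes, with the calcium release channel gene Ryr2 at 23.8 and Myl4 at 44.1 (33.9 and 27.98) in a peak shared with Cdc27, and the myosin genes Myh6 and Myh7 had none.

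**Figure D1:**
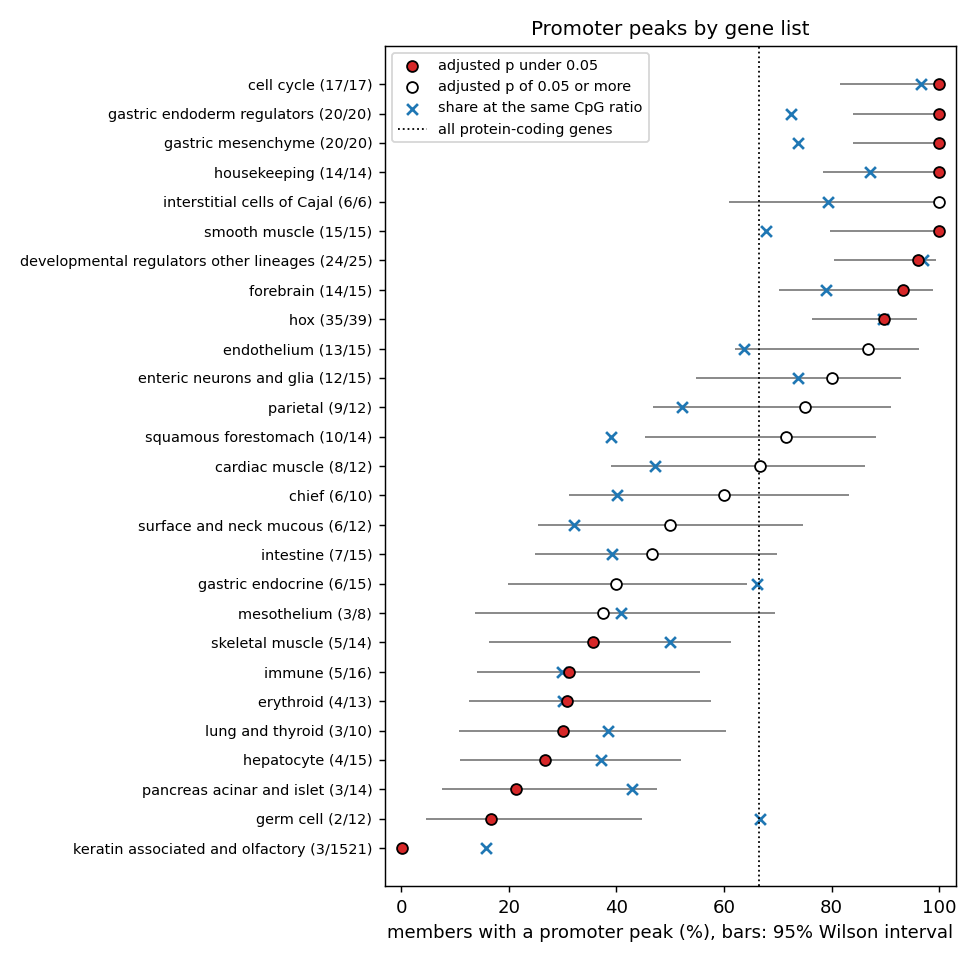
Share of the genes of each list with a promoter peak in the replicated list (circles, x axis in percent, bars the 95% Wilson interval, filled where the adjusted p of Fisher's exact test was under 0.05), the share of genes at the same CpG ratio (crosses) and that of all protein-coding genes (dotted line, 66.6%). Endoderm factors, smooth muscle and mesenchyme reached 100%, and germ cell genes and the olfactory, vomeronasal and keratin-associated families had the lowest shares, at 16.7% and 0.197%.

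Regulators of other lineages carried promoter peaks, with low median folds like those of several gastric lists. A peak was present at 24 of 25 developmental regulators of other lineages (Fisher's exact test, adjusted p = 0.00424) and at 14 of 15 forebrain genes (0.0468). Gsc, a homeobox gene of the gastrula organizer, had 24.1 (19.1 in replicate 1 and 20.6 in replicate 2), Otx1 had 17.6 and Lhx2, a member of both lists, 16.0, whereas Otx2 had a peak in replicate 1 (4.67) but not in replicate 2 or the replicated list and Neurod6 had none. The median fold of members with a peak was 9.35 in the developmental list and 8.97 in the forebrain list, against 31.8 over all genes with a peak. Housekeeping genes (14 of 14, adjusted p = 0.01001) and cell cycle genes (17 of 17, 0.00516) also exceeded other genes by Fisher's exact test, with median folds of 39.5 and 31.7. Ubc, a ubiquitin gene, had 58.5, Actb (beta-actin) 53.0, the proliferation marker Mki67 46.6 and Ccnd2 (cyclin D2) 40.4 (26.7 in replicate 1 and 39.9 in replicate 2). The forebrain call ended in 7 of 10 alternative settings (adjusted p from 0.0344 to 0.595). The housekeeping call ended with only peaks at the starts of 1 gene (0.157, alternatives from 0.00892 to 0.157).

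Across the 4 Hox clusters, genes at the 3′ side had higher H3K4me3 than genes at the 5′ side. All 15 genes of paralogue groups 1 to 5 had a promoter peak, with a median fold of 21.8 (range 2.98 to 33.3), and so did all 8 genes of groups 6 to 8, with a median of 14.6. In groups 9 to 13, 12 of 16 genes had a peak, with a median of 5.61 (range 3.22 to 11.01). Hoxa5 had the highest value of all Hox genes at 33.3 (25.3 in replicate 1 and 30.3 in replicate 2), followed by Hoxa1 at 30.9 (22.4 and 29.8), whereas Hoxa9 had 3.22 and Hoxa11 had 4.10. Hoxb1, with 2.98, was the low exception among groups 1 to 5, and Hoxa13, with 11.01, was the highest of groups 9 to 13. Hoxa10, Hoxc11, Hoxc12 and Hoxd12 had no peak in the replicated list, although Hoxa10 had one in replicate 2 (3.99) and Hoxc12 in replicate 1 (3.62). The mean log2 fold of genes with a peak was 4.26 in groups 1 to 5 and 2.53 in groups 9 to 13, a difference of 1.73 (two-sided permutation test, 100000 resamples, p = 0.00012). Presence of a peak was not separated between these groups in the main setting (Fisher's exact test, p = 0.101). With the start inside the peak, Hoxa9, Hoxa11, Hoxc9 and Hoxd10 lost theirs, and no gene of groups 1 to 5 did. With −log10 q of at least 5, Hoxa9, Hoxb13 and Hoxb1 lost theirs, and with 2000 bp each side Hoxc12 and Hoxd12 gained one. The test of presence was not repeated in these settings. The split into groups was chosen after the values were seen, and neighbouring Hox genes share peaks, so the p-values overstate the independence of the genes. As a list, 35 of 39 Hox genes had a peak (Fisher's exact test, adjusted p = 0.00556), a call that ended in 2 of 10 alternative settings (0.000693 to 0.0910).

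**Figure D2:**
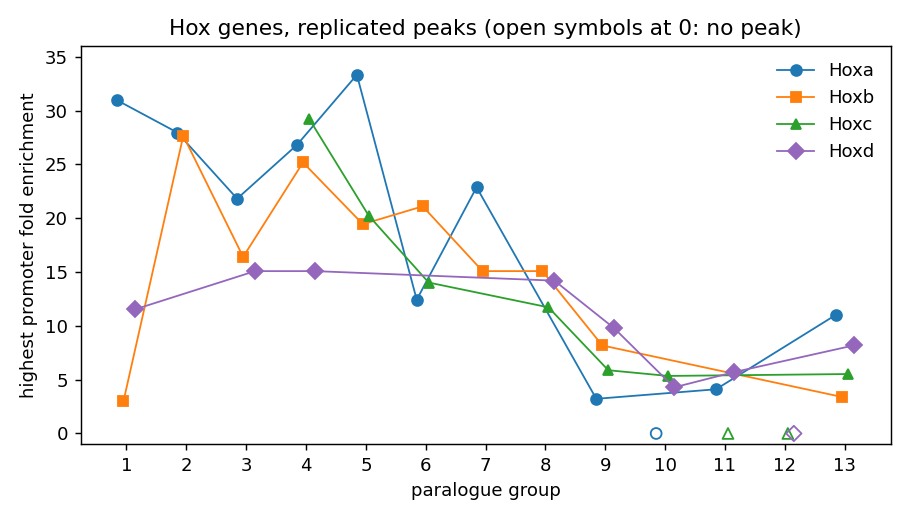
Highest promoter fold enrichment of each Hox gene (y axis) by paralogue group (x axis), with a line for each of the 4 clusters and open symbols at 0 for genes without a replicated peak. Medians were 21.8 in groups 1 to 5 and 5.61 in groups 9 to 13.

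**Figure D3:**
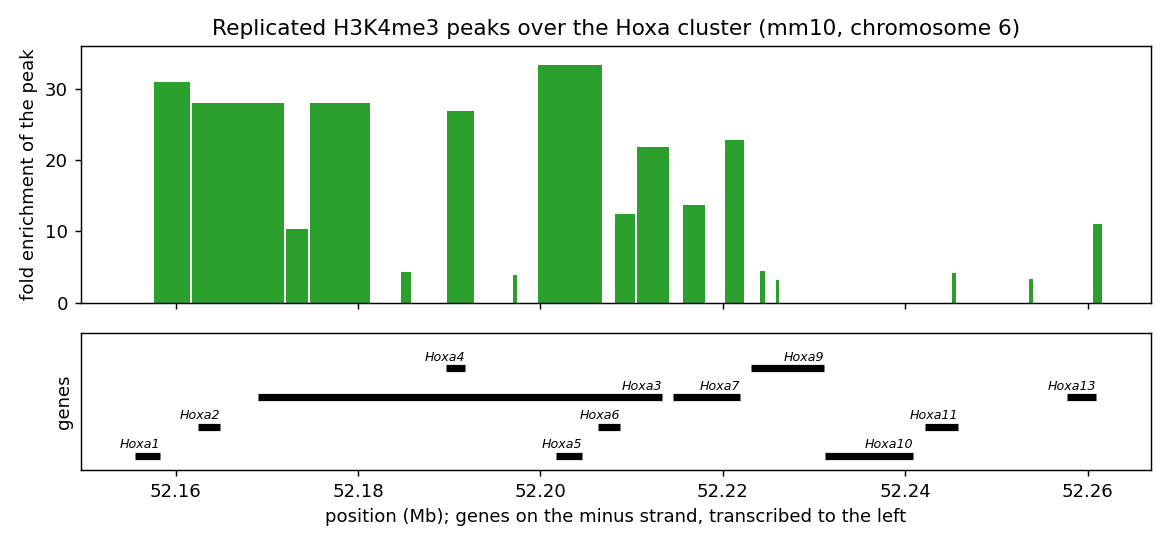
Map of the Hoxa cluster on chromosome 6 (x axis, position in Mb, mm10), with bars for the width and fold enrichment (y axis) of the replicated peaks above the extents of the Hoxa genes, which are transcribed to the left. The highest peaks lie between Hoxa1 and Hoxa7, and the highest peaks near the starts of Hoxa9 and Hoxa11 have folds of 3.22 and 4.10.

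With gaps of up to 1000 bp closed, the widest H3K4me3 domains lay over Nr2f2, over Hoxa1 with Hoxa2, and over Meis2 and Tbx2. The widest, at Nr2f2 (COUP-TFII, a nuclear receptor), covered 25348 bp on chromosome 7 from 70345611 to 70370958 in mm10 and held 8 peaks. It was followed by a domain of 23642 bp over Hoxa1, Hoxa2 and 5730596B20Rik (chromosome 6, 52157669 to 52181310), and by the homeobox genes Meis2 (17310 bp, chromosome 2, 116055712 to 116073021) and Meis1 (14545 bp, chromosome 11, 19007207 to 19021751). Tbx2 (15777 bp), Hoxb5 with Hoxb6 (14063 bp) and Pitx1 (13293 bp) completed the genes with the widest domains. The next 6, named after their values were seen, were the endoderm factors Foxa1 (13196 bp) and Gata6 (11959 bp), Tnrc18 (11779 bp), and the mesenchymal factors Hand2 (11694 bp), Foxf1 (11648 bp) and Isl1 (11294 bp). The median domain was 1511 bp wide, and the widest 5% (995 domains of at least 3772 bp) were called broad. These widths depended on closing gaps of up to 1000 bp between peaks. With gaps of 0 bp the domains had 9662 bp at Nr2f2, 3893 bp at Hoxa1, 10092 bp at Hoxa2, 13167 bp at Meis2, 9968 bp at Tbx2, 10576 bp at Pitx1, 3558 bp at Hoxb5 and 4387 bp at Hoxb6, and only Meis1 kept its width and was the widest of these. With gaps of 3000 bp Hoxb5 and Hoxb6 had 36550 bp. Of 1102 genes with a start in a broad domain, 766 stayed with gaps of 0 bp and 549 with gaps of 3000 bp.

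Broad domains were concentrated in 4 of the 27 lists. By two-sided Fisher's exact test over genes with a start in a domain, they covered a start of 13 of 18 endoderm factors (72.2%, adjusted p = 5.7e-10), 13 of 19 mesenchymal genes (68.4%, 8.37e-10), 11 of 15 smooth muscle genes (73.3%, 5.51e-09) and 12 of 32 Hox genes (37.5%, 1.63e-05). Among other genes with a start in a domain the share was 7.70% in the comparison with endoderm factors. The 12 Hox genes all belonged to the Hoxa and Hoxb clusters. Neighbours among them, such as Hoxa1 with Hoxa2 and Hoxb5 with Hoxb6, lay in the same domain, so the p-value of the Hox list overstates the independence of the genes. Housekeeping and cell cycle genes, with 3 of 14 and 2 of 17, did not pass Fisher's exact test (adjusted p = 0.377 and 0.801). Neither did parietal cell genes (1 of 9, 0.998), developmental regulators of other lineages (2 of 22, 1) or enteric genes (1 of 12, 1). For developmental regulators this depended on the gap, since with gaps of 3000 bp closed 36.4% were in broad domains, against 9.09%, and the list was called (Fisher's exact test, adjusted p = 0.00121). Mucous genes, with 2 of 3 in broad domains (Fisher's exact test, adjusted p = 0.0928), were not called in the main setting but were called without replicate 1 (0.0353). The calls of the endoderm, mesenchymal, smooth muscle and Hox lists were made in all 8 alternative settings, with the highest adjusted p at 0.0103 in the smooth muscle list.

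Most replicated peaks lay at the starts of protein-coding genes. Within 1000 bp of such a start lay 15777 of 22662 peaks (69.6%, 95% Wilson interval 69.0% to 70.2%), against 6.26% ± 0.161 (SD over 100 random placements). These peaks had a median fold of 27.3, compared with 7.47 for 1127 peaks at starts of other annotated genes, 4.28 for 3168 peaks inside genes and 5.52 for 2590 intergenic peaks. The summit of promoter peaks lay a median of 143 bp downstream of the nearest start, and 79.1% lay downstream. A promoter peak was found at 14603 of 21938 protein-coding genes (66.6%, 65.9% to 67.2%), with a median fold of 31.8. Genes with a CpG-rich 5′ end carried it most often, with 99.3% of the 20% of genes highest in the CpG observed over expected ratio and 10.8% of the 20% lowest. The ratio was taken at the 5′ end, while the peak may lie at another start of the gene.

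The gene lists were also set against genes with the same CpG ratio. Smooth muscle genes exceeded such genes by 32.2 percentage points, endoderm factors by 27.5, mesenchymal genes by 26.2, squamous forestomach genes by 32.4 and endothelial genes by 23.0. These lists lay above the central 95% of lists matched on the ratio, endothelial genes narrowly (percentile 97.57). Parietal (22.8), interstitial (20.6), chief (19.9), cardiac (19.5), mucous (17.8), forebrain (14.4) and housekeeping genes (12.9) also exceeded such genes, but within that range. With the ratio at the richest start mucous genes rose to 32.2 (percentile 99.5), outside it. Germ cell genes (-50.1), gastric endocrine genes (-26.1), pancreatic genes (-21.4) and the receptor and keratin-associated families (-15.5) lay below genes at their CpG ratio. For these families the value was -7.59 with the ratio at the richest start. The other lists called below other genes were not separated from genes at their CpG ratio, with immune genes at 1.40, erythroid at 0.776, lung and thyroid at -8.49, hepatocyte at -10.5 and skeletal muscle genes at -14.2 (10.7, 3.33, -3.23, -3.14 and -2.03 with the ratio at the richest start). Hox genes (0.167) and developmental regulators of other lineages (-0.917) lay near the share at their CpG ratio, and at -2.77 and -1.85 with the ratio taken at the richest start. Among members with a peak, the median fold of the developmental regulators was 9.35, against 33.6 in lists matched on the CpG ratio, and that of Hox genes was 14.2 against 30.4. Endoderm factors (16.1 against 25.9, percentile 1.6), enteric genes (12.6 against 28.97, 0.02) and chief (1.32), endocrine (0), squamous (1.03) and endothelial genes (1.71) also lay below the central 95% of such lists. So did intestinal (0.12, 7 genes), cardiac (0.06, 8 genes) and forebrain genes (0, 14 genes). The same held for immune (0.17), pancreatic (0.45), lung and thyroid (0.9) and hepatocyte genes (1.24), but on only 5, 3, 3 and 4 genes. Mucous (3.42), parietal (9.5) and mesothelial genes (16.71), mesenchymal genes (18.5 against 27.6, 2.86), smooth muscle genes (16.7 against 21.8, 16.37) and genes of interstitial cells (25.5 against 26.7, 43.21) lay within the central 95%. Erythroid (16.41), skeletal muscle (32.65), housekeeping (94.56) and cell cycle genes (22.77) and the receptor and keratin-associated families (19.25) also lay within it.

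High peaks were shared between the replicates, and peaks found in 1 replicate were low and narrow. Replicate 2 overlapped 22681 of 29618 peaks of replicate 1 (76.6%, Wilson interval 76.1% to 77.1%), and replicate 1 overlapped 21892 of 26162 peaks of replicate 2 (83.7%, 83.2% to 84.1%). Random placement gave 1.69% ± 0.0759 and 1.92% ± 0.0874 (SD, 100 placements). The 6937 peaks found in replicate 1 alone had a median fold of 3.29 and a width of 235 bp, against 13.2 and 1132 bp for its shared peaks, and 23.5% of them lay at promoters, against 71.7%. The 4270 peaks found in replicate 2 alone had 3.43, 262 bp and 29.3%, against 17.1, 1221 bp and 72.7%. Among the 20% of peaks lowest in fold, 27.6% of replicate 1 peaks and 39.6% of replicate 2 peaks were shared, and among the 20% highest 100% of both. Across 20977 matched peaks, log2 fold enrichments had Pearson's r of 0.963 and Spearman's rho of 0.959, computed across peaks, which are not independent replicates. Fold values were lower in replicate 1 at 79.6% of matched peaks, with a median log2 difference of -0.28 and an SD across peaks of 0.34.

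**Figure D4:**
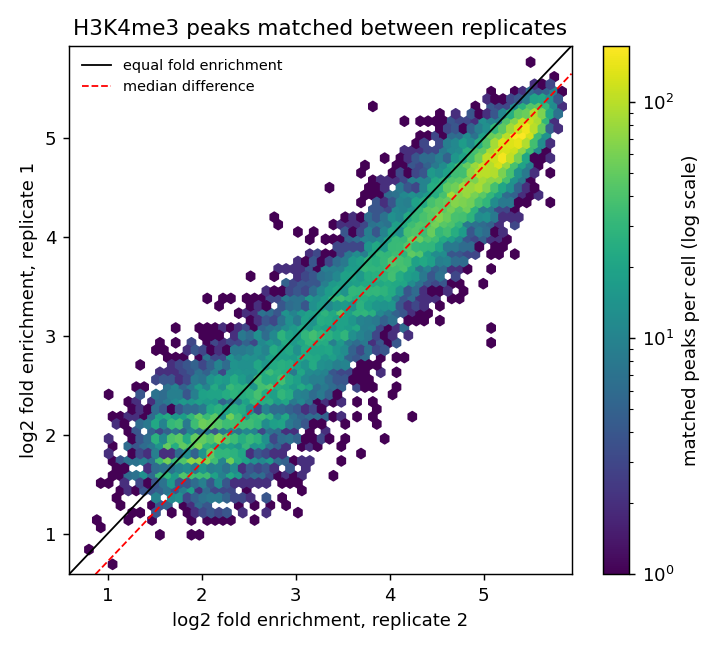
Log2 fold enrichment of the 20977 matched peaks in replicate 2 (x axis) and replicate 1 (y axis), with the colour of each hexagon giving the number of peaks on a log scale, the solid line equal values and the dashed line the median difference of -0.28. The peaks follow the dashed line with Pearson's r of 0.963, and 79.6% of them are lower in replicate 1.

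At the level of genes, few promoters had a peak in 1 replicate alone, and in the main setting none of the 13 cell type lists that could be tested stood apart. Of the protein-coding genes, 14458 had a promoter peak in both replicates, 200 in replicate 1 alone and 187 in replicate 2 alone. After centring on the median over genes, housekeeping genes were lower in replicate 1, with a median log2 difference of -0.12 (lower at 9 of 14 genes, percentile 1.72 of 10000 random lists of similar height, whose central 95% ran from -0.12 to 0.09). That 1 of 17 lists lay outside is no more than chance gives, since 6.31% of simulated lists without a shift did so. Housekeeping genes stayed outside on matched peaks over a start (-0.12, percentile 1.66). With width times fold as the value housekeeping genes lay inside (percentile 3.62), but forebrain genes (0.33, percentile 98.2) and developmental regulators of other lineages (0.38, 99.93) lay outside. The other 16 lists with at least 5 genes in both replicates lay within the range of their random lists, among them smooth muscle at -0.11 and gastric mesenchyme at -0.02. By the highest peak in the window, which may belong to a neighbour, the genes with the largest differences were Zcwpw1 (1.88), Hist1h3a (1.79), Pcdh10 (1.61), Nalcn (1.48) and Prok2 (1.42), higher in replicate 1, and Gp5 (-2.71), Pygm (-2.68), Uba7 (-2.18), Prrt1 (-1.38) and Lypd3 (-1.27), higher in replicate 2. Measured on matched peaks over a start of the gene, Pcdh10, a protocadherin gene, kept 1.61 (fold 17.1 against 7.003), Nalcn, a sodium leak channel gene, 1.48 and Prok2, a secreted prokineticin gene, 1.43, but Uba7 had -0.96 and Prrt1 turned to 0.92. The other 5 had no such matched pair. In the replicated list, the highest window peaks of Pygm and Zcwpw1 also lay at the starts of Rasgrp2 and Mepce, and that of Hist1h3a at the starts of Hist1h1a and Hist1h4a. At Zcwpw1 that peak had a fold of 11.5, against a window value of 26.3 in replicate 1 and 8.90 in replicate 2. With 2000 bp each side Zcwpw1 was assigned 40.2, so a higher peak lay beyond its 1000 bp window. Among all genes with matched peaks over a start, the largest differences were 1.82 at Srd5a1 and -1.35 at Prr13, both named after their values were seen. With 1 library per replicate these differences have no replicate check, and each fold is relative to the background of its own list.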

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

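The test of peak height at forebrain genes and developmental regulators, and the test of gastric endocrine genes by themselves, were chosen only after the result was seen. Data outside the comparisons held 14 replicated peaks on 5 scaffolds that are not placed on a chromosome, with a median fold of 4.57 and a highest fold of 28.5. Of these, 12 had a −log10 q of at least 5, and no annotated start was compared with them.

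Replicate 1 had more peaks than replicate 2, and a larger share of them was weak (13.8% against 9.90% with −log10 q under 2). Among peaks with −log10 q of at least 5 the ratio of peak numbers was 0.999, so the excess lay in calls nearer to the caller's threshold, which is what such calls as a source would give. Because the pattern was already one of weaker peaks, this ratio does not set that source apart from others. A second explanation, that domains were split into more peaks in replicate 1, stays open, since after closing gaps of up to 1000 bp the ratio of domain numbers was 1.097, between the bounds set for and against it. For a difference in cell composition between the stomach pools, 0 cell type lists lay outside their random range, which met the bound of at most 1 that had been set against it. With width times fold as the value, forebrain genes, a list of another tissue, lay outside (0.33, percentile 98.2). The bound set against a difference in composition was met only for the 13 of 22 cell type lists with enough genes to be tested. The mucous, mesothelial, immune and erythroid lists were among those not tested. This limit was stated after the value was seen. A difference in composition may remain, and the extra source file cited for replicate 1 was not tested.

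At forebrain genes and developmental regulators of other lineages, which carried low promoter peaks, the share with a peak was 94.9%, which is 4.88 percentage points above the 90.0% of genes at the same CpG ratio, so CpG content of the promoter may account for the presence of the peaks, although forebrain genes alone lay 14.4 points above. With the CpG ratio taken at the richest start these values were 0.461 and 4.39. CpG content does not account for their height, as the median fold was 8.89 against 31.4 in lists matched on the CpG ratio, a ratio of 0.283 at percentile 0 of 10000 matched lists. Low height was not particular to these lists, since endocrine (5.96 against 28.01), enteric (12.6 against 28.97) and endoderm genes (16.1 against 25.9) also lay below matched lists. Signal from a minority of cells and low marking in many cells both stay open, and no biological explanation was tested because the design has 1 group.

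In the lists of mucous, chief and endocrine genes several members lacked a promoter peak, among them Muc5ac, Gif, Gast and Sst. Over mucous, chief and endocrine genes together 48.6% had one, 0.58 percentage points above the share at the same CpG ratio, but this joins 17.8 points in mucous and 19.9 in chief genes with the opposite sign in endocrine genes (32.2, 25.9 and jointly 6.64 with the CpG ratio at the richest start), so it leaves the CpG content of the promoter open for the lists as a whole, a reason given after the value was seen. Gastric endocrine genes by themselves lay at -26.1 percentage points (40% against 66.1%, percentile 0.41), which argues against CpG content as the cause in this list, and the value was -26.7 at the richest start. Rarity of endocrine cells in whole stomach, with signal under the peak threshold, is a hypothesis without a test here. Named after their values were seen, Tph1 and Chga had a promoter peak in replicate 1 but not replicate 2, and Ddc the reverse.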

How the results depend on the processing

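The tests that required −log10 q of at least 5 in the counted list alone, a start inside the peak, peaks at the starts of 1 gene, or matched peaks over a start were chosen only after the result was seen. No paired analysis was possible because the series has 1 group. No list call changed direction in any alternative. The shared share of replicate 1 and replicate 2 peaks was 79.8% and 86.7% with an overlap of 1 bp, 66.3% and 75.1% with 50% of both peaks, 94.3% and 93.2% with −log10 q of at least 5, 92.3% and 91.1% for the 20000 highest peaks, and 98.5% and 98.5% with −log10 q of at least 5 in the counted list and any peak in the other. Pearson's r was 0.964 with 1 bp, 0.951 with −log10 q of at least 5 and 0.968 on the log10 of −log10 p. The share of peaks at promoters was 73.6% with 2000 bp, 75.1% with −log10 q of at least 5, 62.0% in the pooled list, 60.4% to 65.6% without 1 replicate, 57.9% with the gene's 5′ end and 62.6% with the start inside the peak. The share of genes with a promoter peak was 66.1% with 500 bp, 67.2% with 2000 bp, 65.5% with −log10 q of at least 5, 67.6% in the pooled list, 66.8% at the lowest and 66.8% at the highest without 1 replicate, 62.9% with the 5′ end, 64.4% with the start inside the peak and 54.3% with peaks at the starts of 1 gene, where fewer peaks are used by construction. Of 16 called lists, 9 passed in every alternative, and the number called ranged from 13 to 18. In 17 instances a list lost its call and in 8 it gained one, the gains being endocrine (2 of 10 alternatives, adjusted p from 0.0260 to 0.685), mesothelium (2), intestine (2), mucous (1) and endothelium (1). Broad domains were called in 4 or 5 lists, with developmental regulators added when gaps of 3000 bp were closed and mucous genes without replicate 1. With width times fold as the value, 2 lists lay outside their random range in the replicate comparison, forebrain (0.33) and developmental regulators (0.38), and housekeeping did not; the cause was not tested. Of 102 named genes with a peak, 12 lost it with the start inside the peak and 13 with peaks at the starts of 1 gene. With 2000 bp each side, 4 named genes without a peak gained one. The depth is unknown, so a missing promoter peak means that no peak was listed, not that the mark was absent.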

Other observations

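The test of the X-linked homologues was set before its values were seen, and the domains and genes named here were chosen only after the result was seen. Non-coding genes also carried wide H3K4me3 domains. Of the broad domains, 38 held no protein-coding start, and 23 of these held the start of another annotated gene. Some of the 38 ended close to a protein-coding start, such as 4 bp from that of Dnmbp and 126 bp from that of Shh. The widest, 11202 bp on chromosome 18 from 61655162 to 61666363, covered the start of Carmn, a long non-coding RNA gene of smooth muscle that is followed on the same strand by Mir143 (61649196 to 61649258) and Mir145a (61647825 to 61647894), microRNAs known from smooth muscle. Its highest fold was 20.5 (16.2 in replicate 1 and 19.5 in replicate 2), and the nearest protein-coding start, of Il17b, lay 18524 bp away. The next were 8597 bp at Neat1 and 8297 bp at Malat1, nuclear non-coding RNAs on chromosome 19, with highest folds of 20.9 and 31.8. A domain of 5899 bp on chromosome 9 (41579476 to 41585374) held Mir125b-1.

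Across annotated gene types, a peak within 1000 bp of a start was found at 178 of 190 bidirectional promoter lncRNA genes (93.7%) and 819 of 5854 lincRNA genes (13.99%), or 8.35% of the lincRNA genes whose starts lay away from protein-coding starts. Only 1 of the bidirectional promoter lncRNA genes lay away from protein-coding starts, and it had no peak, so their share reflects the promoters of coding neighbours. None of 218 immunoglobulin and 144 T cell receptor variable genes had one. The highest peaks away from annotated starts included one of fold 46.8 on chromosome 8 (69715434 to 69717019), 4710 bp from the nearest coding start, of Zfp869, and one of fold 44.7 inside Lncppara on chromosome 15 (85669607 to 85674962).

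Y-linked genes had lower fold enrichment in replicate 1 than in replicate 2. The values were 8.56 and 11.5 at Kdm5d, 4.61 and 12.4 at Eif2s3y, 7.90 and 13.5 at Uty, and 6.25 and 14.6 at Ddx3y, and Xist went the other way with 17.4 and 11.5. The median centred log2 difference of the 4 Y-linked genes was -0.68, outside the random range of -0.27 to 0.44. A lower share of males in the pool of replicate 1 is a hypothesis that may account for this, since both pools are labelled as mixed sex. It predicts higher values in replicate 1 at the X-linked homologues that escape X inactivation, and these had a median of 0.15 (Kdm5c 0.18, Eif2s3x 0.49, Kdm6a 0.05 and Ddx3x 0.13), above the bound of 0.1 set for it but within the random range of -0.20 to 0.18. All 468 X-linked genes together had the opposite sign, with a median of -0.02, below their random range of 0.02 to 0.08. These genes were not chosen for escape from X inactivation, so their median does not test the prediction. The hypothesis stays open, since the homologues lay within their random range. The peaks of separate lists are relative to separate backgrounds, and the sex ratio of the pools is not stated in the labels.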
